A study of Caenorhabditis elegans with 14 samples.

How the data were processed

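The series holds 14 samples. Small RNA sequencing of 2 of them, 1 library from control RNAi and 1 from snpc-4 RNAi young adults, was used. The other 12, from chromatin immunoprecipitation and its inputs, were not analysed here. Per the labels' protocols, RNA was made into libraries with the Illumina small RNA v1.5 kit and inserts of 22 to 30 nucleotides were sequenced; the labels differ on the larval stage at which feeding began. Reference piRNAs are 21 nucleotides long, just under that stated range. The submitters' processing notes name BWA. Its version, the genome build, the annotation and the counting tool are not given in the sources used here.

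Per the file headers, the deposited tables give for each transcript a read count and a value in RPM. The counts are whole numbers. The RPM values equal the count divided by 1 constant per library, which gives 20413480 reads for control and 20875010 for snpc-4 RNAi. What those totals count is not given in the sources used here. The listed transcripts hold 956653 and 1074622 counts. One read is worth 0.0490 RPM in the control library and 0.0479 RPM in the other, and the floor of 3 counts is 0.147 and 0.144 RPM.

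Names came from a RefSeq gene table of assembly WBcel235, matched on locus tag or symbol. All but 20 transcripts matched, among them 15363 of 15366 piRNAs. A microRNA transcript was matched after removal of its final letter, which marks a mature product, so a family can hold more transcripts than genes. The build behind the counts is unknown, so no gene coordinates are printed. Besides names and the piRNA length, the table was used to place piRNAs in the chromosome IV domains, whose borders were fixed in advance, to follow the order of listing and to find microRNA genes close to each other.

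Totals were compared as deposited RPM. Per transcript, the log2 ratio was computed from counts with 1 read added, divided by the RPM totals, for a mean over both libraries of at least 10 counts. The plan named deposited normalized values and a pseudocount of 1 without its unit. Because counts were deposited too, the read was taken as the unit, after the tables had been examined; 1 RPM, and a minimum of 10 RPM with it, were added as alternatives. Intervals for counts are exact Poisson intervals, for ratios exact conditional binomial intervals, for shares exact Clopper-Pearson intervals and for medians exact order-statistic intervals, all at 95%. List medians were set against 10000 random lists matched on mean count, in 10 bins for piRNAs and 4 for microRNAs. With 1 library per group no test was run.

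Named transcripts followed a rule fixed before the data were examined, as were the lists and the alternatives, apart from those with 1 RPM, the median ratio of transcripts other than piRNAs, the totals per run of listing, and the totals of piRNA position groups and of tRNAs without their most abundant members, which were chosen after seeing the data. The rule takes the 6 highest means, the 6 lowest and 6 highest ratios among transcripts with a mean of at least 50 counts, a set of known piRNAs, and the 2 most abundant members of each list. Alternatives changed the scaling, the minimum, the pseudocount, the number of abundance classes, the detection limit and the most abundant piRNAs. Another took all of chromosome IV as 1 list, and the domain borders were not moved. The upstream motif of piRNA genes needs a genome and was not analysed here, nor were protein-coding gene lists, rRNA or snRNAs by U number, which these tables do not name.

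The steps were tested on simulated data drawn from the measured means. Of 100 piRNAs simulated 2-fold lower, 80 passed the minimum and had a median log2 ratio of -1.02, and 41 came out at least 2-fold lower. Of 100 simulated 4-fold lower, 70 passed, with a median of -1.85, and 69 came out at least 2-fold lower. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.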

Results

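Small RNAs were sequenced from whole young adult Caenorhabditis elegans of the wild-type strain N2 after RNA interference by feeding. Larvae ate bacteria carrying either the empty vector L4440, as control RNAi, or a construct against snpc-4. SNPC-4, formerly GEI-11, is the worm's counterpart of the largest subunit of the SNAP complex, which binds promoters of small nuclear RNA genes. The comparison asks how piRNAs and other small RNAs differ when snpc-4 is depleted. Each group has 1 library, so the differences have no replicate check, no p-value is given, and each statement compares 2 libraries rather than 2 conditions. Intervals are 95%. Those of counts and ratios cover counting error only, and may be too narrow, since PCR reads without molecular identifiers are not independent molecules. Those of medians and of shares of transcripts treat transcripts as a sample, and measure no variation between animals or libraries. The snpc-4 mRNA is not among the listed transcripts, so the depletion itself was not analysed here.

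The tables list 15366 piRNAs, 203 microRNAs, 118 small nuclear RNAs (snRNAs), 342 small nucleolar RNAs (snoRNAs) and 612 tRNAs. The listed counts sum to 956653 in the control library and 1074622 in the snpc-4 library. Deposited RPM values, counts scaled to the library total, rest on larger totals, 20413480 and 20875010 reads, of which the listed transcripts hold 4.69% and 5.15%. A count of 0 allows up to 0.147 RPM in the control library and 0.144 RPM in the snpc-4 library, 3 counts of each total.

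The piRNAs, small RNAs of the germline bound by the Argonaute PRG-1 and called 21U-RNAs in worms, were lower in the snpc-4 library. Their summed abundance was 3176 RPM (3151 to 3200) in the control library and 1537 RPM (1520 to 1554) in the snpc-4 library, a ratio of 0.484 (exact interval 0.478 to 0.491). They made up 6.78% of the listed counts in the control library and 2.99% in the snpc-4 library. The most abundant piRNA, 21ur-908, had 7881 and 2673 counts, a ratio of 0.332 (0.317 to 0.347). The next, 21ur-5815 (T23G4.79), had 3046 and 2740 counts, a ratio of 0.880 (0.835 to 0.927).

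Most single piRNAs were lower too. Of the 560 piRNAs with a mean of at least 10 counts, 502 were lower in the snpc-4 library and 58 higher. Their median log2 ratio was -1.11 (exact interval of the median -1.18 to -1.03), with quartiles of -1.54 and -0.51. At least 2-fold lower values were found for 312 piRNAs and at least 2-fold higher values for 5. Named after their values were seen, these 5 were 21ur-3826 (7 and 22 counts), 21ur-15093 (6 and 23), 21ur-4611 (14 and 38), 21ur-2860 (4 and 17) and 21ur-7374 (14 and 40). The interval of the ratio lay below 1 for 328, above 1 for 8 and included 1 for 224. In simulated libraries with counting noise and no change, 9 of 571 piRNAs came out at least 2-fold lower and 12 at least 2-fold higher. Of 80 piRNAs above the minimum that were simulated 2-fold lower, 41 reached that limit. The 6 lowest ratios among all transcripts with a mean of at least 50 counts were all piRNAs. They were 21ur-8984 (Y9C9A.88; 102 and 14 counts, ratio 0.134, 0.0709 to 0.236), 21ur-3078 (H32C10.22; 264 and 40), 21ur-4181 (ZK616.18; 93 and 18), 21ur-3801 (C47A4.59; 92 and 18), 21ur-4658 (C10G6.14; 347 and 79) and 21ur-1868 (93 and 21). Plain ratios and their intervals add no read, while the log2 ratio adds 1 read to each count. With 1 RPM added in place of that read, a choice made after seeing the data, the median was -0.56. In that case 106 piRNAs were at least 2-fold lower. Scaled by the median ratio of all transcripts above the minimum, 438 were lower and 121 higher. piRNAs are 560 of the 1109 transcripts that set this median, so it takes up part of their own difference and raises every other class with it. With the median of the 549 others, of which 333 are tRNAs, a choice made after seeing the data, 502 piRNAs were lower and 58 higher, and no class, family or position total had the opposite direction to RPM.

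**Figure D1:**
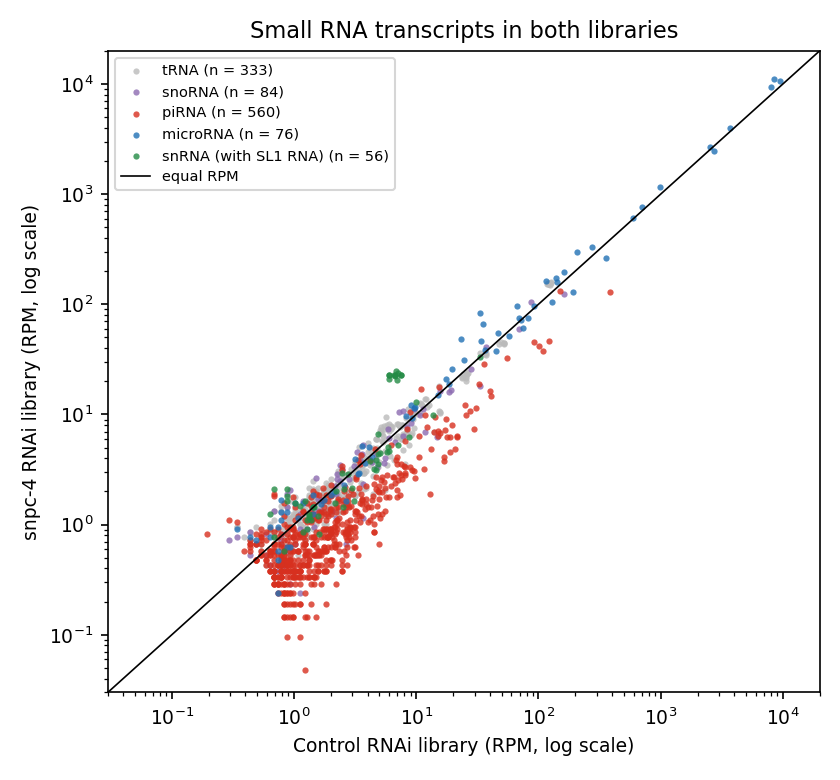
Each point is a transcript with a mean of at least 10 counts, at its RPM in the control RNAi library (x axis) and the snpc-4 RNAi library (y axis), both on log scales, coloured by RNA class; the line marks equal values. Most of the 560 piRNAs lie below the line, and a cluster of SL1 RNA copies lies above it.

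More piRNAs were detected in the control library than in the snpc-4 library. Among 15366 listed piRNAs, 2320 had reads in both libraries, 1018 in the control library alone and 595 in the snpc-4 library alone, while 11433 had none in either. Most of those seen in a single library had few reads: 4 had at least 10 counts in the control library and 0 in the snpc-4 library, and 0 had the opposite pattern. Those 4, named after their values were seen, were 21ur-3935 (19 counts), 21ur-8421 (13), 21ur-3949 (11) and 21ur-254 (10). The piRNAs fixed in advance as often measured in published work were at or under the floor in both libraries. 21ur-1, 21ur-1848, 21ur-3442, 21ur-3372 and 21ur-2921 had 0 counts in each. 21ur-5045 had 1 count in the control library and 0 in the other, and 21ur-1258 had 0 and 2, so no fold is given. 21ux-1 is not among the names matched here.

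Worm piRNA genes lie mostly in a pair of broad domains on chromosome IV, and piRNAs of both domains were lower in the snpc-4 library. In the left domain, from 4 to 7 Mb, the total ratio was 0.374 (0.357 to 0.392) and the median log2 ratio of 66 piRNAs was -1.35 (-1.82 to -1.02). Its most abundant members were 21ur-2935 (B0350.6), with 606 and 153 counts, and 21ur-1779 (C06E7.33), with 426 and 102. In the right domain, from 13 Mb to the end, the total ratio was 0.485 (0.479 to 0.492) and the median of 473 piRNAs was -1.12 (-1.18 to -1.03). piRNAs elsewhere on chromosome IV had a total ratio of 0.735 (0.645 to 0.837), and those of other chromosomes a ratio of 1.04 (0.944 to 1.14), below 1 when scaled to the listed counts or the microRNA total. Each of these 2 values leaned on 1 piRNA, as a comparison made after seeing the data showed. Without 21ur-9757 the ratio for other chromosomes was 0.866 (0.774 to 0.969), and without 21ur-14550 that for chromosome IV outside the domains was 0.865 (0.745 to 1.00). Examples are 21ur-14550 (H23L24.8; 162 and 71 counts) and 21ur-11668 (F33D4.9; 66 and 54) on chromosome IV outside the domains, and 21ur-9757 (F31A9.7; 224 and 353) and 21ur-13507 (Y22D7AR.15; 94 and 101) on other chromosomes. Against 10000 random piRNA lists of equal size and matched mean, 0.57% had a median at or below that of the left domain and 33.0% at or below that of the right domain. The values were 99.2% for the 10 piRNAs elsewhere on chromosome IV (median -0.29, -0.50 to 0.50) and 99.5% for the 11 of other chromosomes (median -0.24, -1.53 to 0.62). Both small groups had a positive median when scaled by the median ratio, 0.14 and 0.19. The random lists were drawn from all 560 piRNAs above the minimum, of which the right domain supplies 473. Its share of 33.0% therefore compares the right domain mostly with itself.

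**Figure D2:**
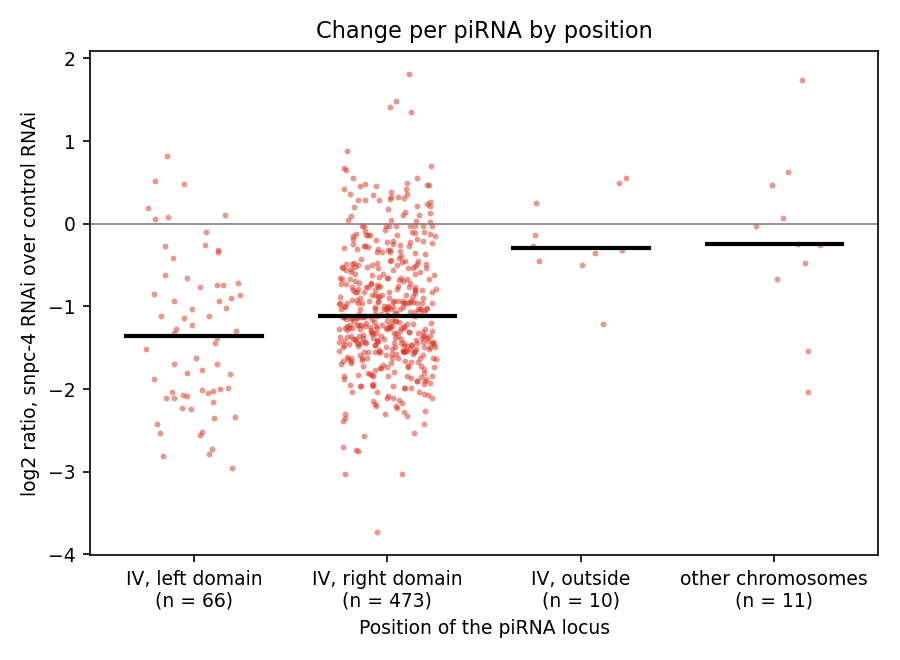
Points are the log2 ratios, snpc-4 RNAi over control RNAi, of piRNAs with a mean of at least 10 counts, grouped by position; black bars are medians. The medians are -1.35 and -1.12 in the left and right domains of chromosome IV, and -0.29 and -0.24 outside them and on other chromosomes.

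Among piRNAs with a mean of at least 10 counts, abundant and less abundant members were both lower. In 4 classes of 140 piRNAs by mean count, the median log2 ratio was -0.95 (-1.11 to -0.77), -1.06 (-1.25 to -0.85), -1.13 (-1.32 to -0.99) and -1.26 (-1.35 to -1.14) from the lowest to the highest class. The most abundant members were 21ur-7439 (C25G4.12; 11 and 17 counts) and 21ur-405 (H08M01.54; 19 and 9) in the lowest class, 21ur-3717 (C24D10.21; 37 and 8) and 21ur-5803 (C49A9.24; 29 and 16) in the next, and 21ur-9331 (F55B11.124; 63 and 20) and 21ur-4207 (47 and 36) in the third. The highest class is led by 21ur-908 and 21ur-5815. The highest class minus the lowest was -0.31, with outer bounds of -0.58 and -0.029; it was -0.010 with a minimum mean of 50 counts and -1.02 with a minimum mean of 1. At that minimum the lowest class, of 723 piRNAs with means up to 1.5 counts, had a median of -0.032. That is the value of any transcript with equal counts in both libraries. Of these 723 piRNAs, 261 were at least 2-fold lower and 104 at least 2-fold higher.

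microRNAs, short regulators of mRNA, made up 84.9% of the listed counts in the control library and 88.8% in the snpc-4 library. Their total was 39808 RPM (39721 to 39895) and 45738 RPM (45646 to 45830), a ratio of 1.15 (1.15 to 1.15). The 6 transcripts with the highest mean were all microRNAs: mir-84 (ratio 1.13), mir-1 (1.31), mir-48 (1.18), mir-80 (1.07), mir-82 (1.05) and mir-58.1 (0.906). Among 76 microRNAs above the minimum, 51 were higher and 25 lower, against 37 and 39 when scaled to the microRNA total. The let-7 family, which times larval development, had a total ratio of 1.16 (1.15 to 1.16), led by mir-84 (191953 and 222719 counts) and mir-48 (163287 and 197065). mir-1, a muscle microRNA, had 172025 and 230145 counts, and mir-71 had 14394 and 15789. With them, the tissue list had a ratio of 1.29 (1.28 to 1.30); its neuronal members mir-124 and lsy-6 had 0 counts in both libraries.

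The mir-35 family, expressed in oocytes and embryos, had few reads and was lower in the snpc-4 library. Its 8 members summed to 54 and 16 counts, a ratio of 0.290 (0.155 to 0.514), with 15 and 5 for mir-35 and 10 and 6 for mir-37. The mir-2 family had a ratio of 0.764 (0.740 to 0.788), with 7305 and 5470 counts for mir-250 and 1690 and 1556 for mir-2; it was 0.039 on the log2 scale, the opposite direction, when scaled by the median ratio. The mir-64 family had a ratio of 1.36 (1.23 to 1.49), with 692 and 963 counts for mir-229 and 18 and 13 for mir-66. The mir-51 family had 1.12 (1.09 to 1.16), below 1 when scaled to the microRNA total, with 3312 and 4108 counts for mir-53 and 2919 and 3357 for mir-54. The mir-58 family had 1.02 (1.01 to 1.02), led by mir-80 (75560 and 82669) and mir-82 (52129 and 56096), and lay below 1 when scaled to the listed counts or the microRNA total. The mir-44 family had 0.947 (0.894 to 1.00), above 1 by the median ratio, with 1474 and 1517 counts for mir-45 and 909 and 791 for mir-61. In the lin-4 family, mir-237 had 15 and 12 counts and lin-4 had 0 in both, a ratio of 0.782 (0.334 to 1.79), so no difference was detectable with these counts. Against random microRNA lists of matched mean, the share with a median at or below the list's was 71.9% for let-7, 49.2% for mir-51, 35.9% for mir-58, 7.21% for mir-44, 68.1% for mir-64, 2.09% for mir-2 and 75.2% for the tissue list. The lin-4 and mir-35 lists each had 1 member above the minimum, with 25.6% and 5.14%. The mir-44, mir-2 and tissue lists each had 2 such members and the mir-64 list 3, so their shares rest on few microRNAs.

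**Figure D3:**
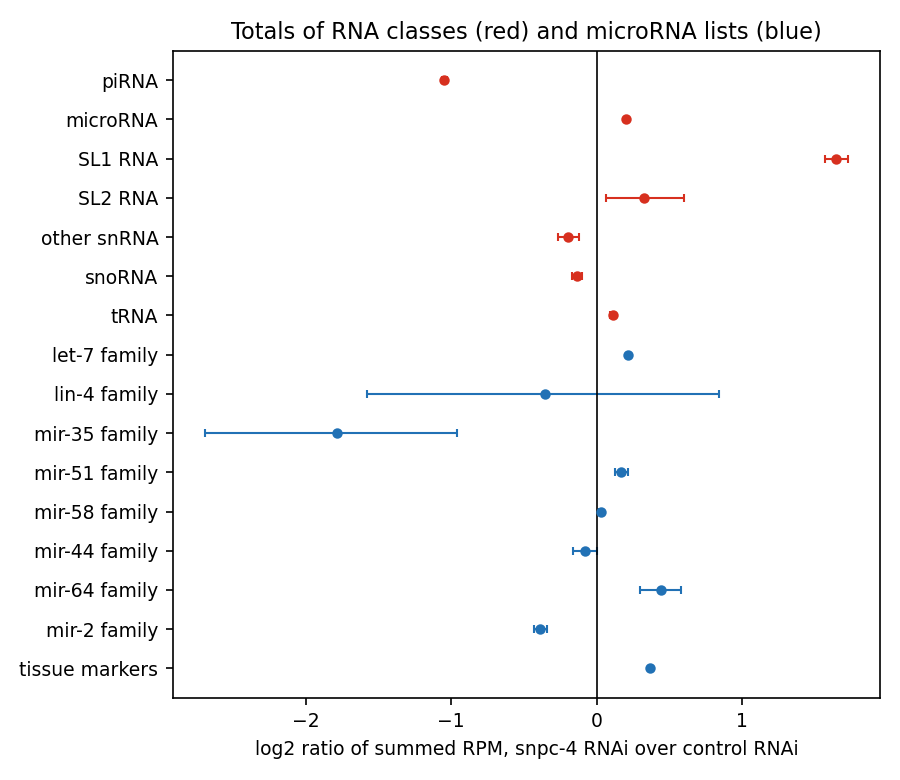
Points are log2 ratios of summed RPM, snpc-4 RNAi over control RNAi, for RNA classes (red) and microRNA lists (blue), with 95% counting intervals; the vertical line marks no difference. The piRNA total lies at -1.05, the SL1 RNA total at 1.64 and the microRNA total at 0.20; the mir-51, mir-58 and tRNA totals change sign when scaled to the microRNA total, and the lin-4, mir-44, mir-2, other snRNA and snoRNA totals when scaled by the median ratio.

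Reads of SL1 RNA, the leader RNA that is spliced onto most worm mRNAs, were higher in the snpc-4 library. The 12 listed copies summed to 1711 and 5472 counts, a ratio of 3.13 (2.96 to 3.30). The 6 highest ratios among all transcripts with a mean of at least 50 counts were SL1 copies: sls-1.8 (Y102A5D.20; 123 and 481 counts, ratio 3.82, 3.13 to 4.70), sls-1.4 (123 and 472), sls-1.9 (139 and 516), sls-1.2 (122 and 439), sls-1.7 (134 and 472) and sls-1.5 (137 and 476). The copy with the next highest mean after sls-1.9 was sls-1.10 (145 and 493). The exception was sls-1.12, with 203 and 273 counts, named after its values were seen. SL1 copies are near-identical, so their single counts are uncertain and their sum is the safer value. SL2 RNA, the other spliced leader, had 208 and 267 counts, a ratio of 1.26 (1.04 to 1.51), led by sls-2.13 (100 and 140) and sls-2.3 (18 and 38). Of its 5 members above the minimum 3 were higher and 2 lower; the lower ones, named after their values were seen, were sls-2.10 (28 and 23) and sls-2.5 (24 and 18).

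The remaining classes differed little. Other snRNAs had a total ratio of 0.873 (0.830 to 0.918), with 684 and 688 counts for F10D2.13 and 279 and 208 for F15H9.6. The snoRNAs had 0.910 (0.889 to 0.931), with 3307 and 2568 counts for F47G4.9 and 1777 and 2183 for ZK265.10. Both classes lay above 1 when scaled by the median ratio, of which piRNAs set a large part, and below 1 with the median of the other transcripts. The tRNAs had 1.08 (1.07 to 1.09), with 2583 and 3310 counts for ZK783.t1 and 2569 and 3245 for C39D10.t2, and lay below 1 when scaled to the listed counts or the microRNA total. The 10 most abundant tRNA transcripts had nearly equal counts, between 2419 and 2583 in the control library, and may share reads, so their single counts are uncertain. Without them, a comparison chosen after seeing the data, the tRNA ratio was 0.945 (0.931 to 0.959), the opposite direction. Of 333 tRNAs above the minimum, 173 were lower and 160 higher. The split was 218 and 115 when scaled to the listed counts, and 239 and 94 to the microRNA total. By the median ratio it was 68 and 264. In the control and snpc-4 libraries, tRNAs made up 6.20% and 6.09% of the listed counts, snoRNAs 1.54% and 1.28%, SL1 RNA 0.179% and 0.509%, SL2 RNA 0.0217% and 0.0248%, and other snRNAs 0.336% and 0.267%.

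Many listed microRNAs, snRNAs, snoRNAs and tRNAs had no reads in either library, and these followed the order of listing. Within each class and chromosome the transcripts are listed in at most 2 runs of ascending position. Of 634 transcripts in the first runs, 49.8% (exact interval 45.9% to 53.8%) were at 0 in both libraries, against 3.69% (2.35% to 5.49%) of 623 in the second runs. lin-4, mir-124, lsy-6, the whole mir-35 family, the whole mir-64 family and sls-1.12 are in first runs, while the let-7 family and the other SL1 copies are in second runs. A count of 0 is therefore read here as no count in these tables, not as absence of the RNA. The ratios also differed between the runs, in a comparison chosen after seeing the data. For microRNAs the total ratio was 0.913 (0.902 to 0.924) in first runs, with 57233 and 53446 counts, and 1.17 (1.16 to 1.17) in second runs, with 755383 and 901331. The first value turns on mir-58.1, without which it was 1.21 (1.12 to 1.30), and the medians of -0.072 (-0.15 to 0.60) for 15 microRNAs and 0.23 (0.057 to 0.28) for 61 have overlapping intervals. For tRNAs the ratios were 0.905 (0.873 to 0.938) and 1.10 (1.09 to 1.11). ZK783.t1 and C39D10.t2, among the 10 most abundant tRNAs, are in second runs, and without those 10 all tRNAs had 0.945 (0.931 to 0.959). The tRNA medians of -0.11 (-0.23 to 0.15) in first runs and -0.032 (-0.070 to 0.057) in second runs have overlapping intervals. For other snRNAs the ratios were 1.47 (1.19 to 1.81), on 155 and 233 counts, and 0.839 (0.795 to 0.885). For snoRNAs they were 0.891 (0.810 to 0.981) and 0.911 (0.889 to 0.933). The first-run snoRNA value turns on M163.14, without which it was 1.13 (1.01 to 1.26). The piRNAs are not listed by position, so the comparison of runs could not be made for them.

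**Figure D4:**
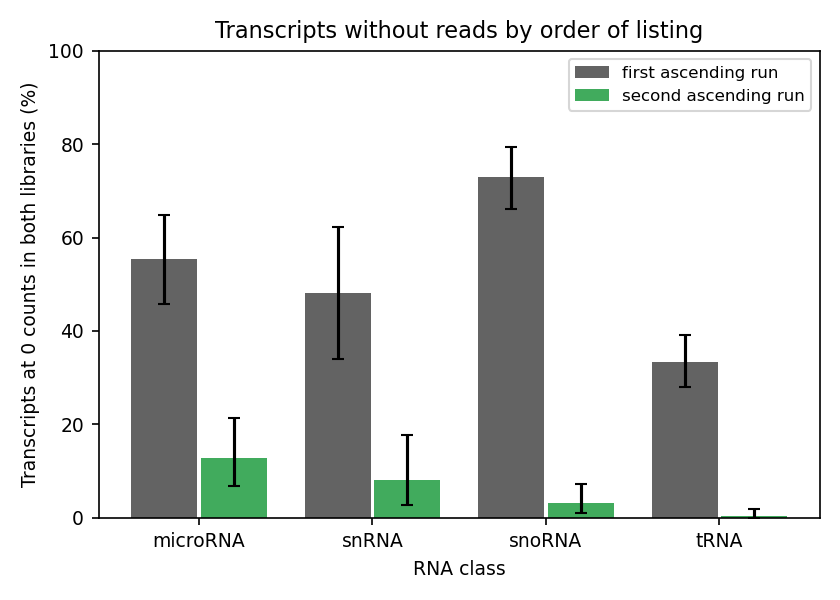
Bars give the percentage of transcripts at 0 counts in both libraries, from 0 to 100 on the y axis, for microRNA, snRNA, snoRNA and tRNA, in the first (grey) and second (green) ascending run of each chromosome; error bars are exact 95% binomial intervals. The share is higher in the first run in each class, at 55.5% against 12.9% for microRNA and 73.1% against 3.13% for snoRNA.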

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

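Of 143 alternative values, 75 kept the sign and stayed within the interval of the reported value or within 1.5 times the reported count, 57 kept the sign but lay outside it or outside 1.5 times the count, and 11 changed sign, 4 of them within the interval; the cause was not tested except where named. Those with 1 RPM, the median ratio without piRNAs, the runs of listing, and the position and tRNA totals without their most abundant members, were chosen after seeing the data. Relative to RPM, every log2 ratio shifts by -0.14 with scaling to the listed counts, 0.43 with the median of ratios, -0.20 with the microRNA total and 0.014 with the median of ratios without piRNAs. The 143 values leave out the median of ratios and the microRNA total for families and non-piRNA classes, and every rescaling of position totals. Sign changes of that kind, given in the Results, come on top of the 11.

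The log2 ratio of the piRNA total, below 0 throughout, was -1.18, -0.62 and -1.25 under the first 3 scalings and -1.01 without the 10 most abundant piRNAs. The median per piRNA was -1.25, -0.68 and -1.31 under these scalings, -0.62 and -1.27 with minimum means of 1 and 50, -0.92 with a pseudocount of 5, -0.56 with 1 RPM and -1.24 with 1 RPM and a minimum of 10 RPM, which leaves 35 piRNAs. The number at least 2-fold lower was 178 by the median of ratios, 1218 and 84 with minimum means of 1 and 50, 106 with 1 RPM and 23 with 10 RPM; the number at least 2-fold higher was 11, 204, 0, 0 and 0. The minimum sets how many piRNAs enter.

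The left domain's median was -0.92 by the median of ratios, -0.76 and -2.03 with minimum means of 1 and 50, -0.64 with 1 RPM and -1.88 with 10 RPM. The right domain's was -1.26, -0.69 and -1.32 under these scalings, -0.68 and -1.27 with minimum means of 1 and 50, -0.93 with a pseudocount of 5 and -0.57 with 1 RPM. Elsewhere on chromosome IV it was 0.14 by the median of ratios and -0.76 for 2 piRNAs at a minimum of 50. On other chromosomes it was 0.19 by the median of ratios, 0.47 for 3 piRNAs at a minimum of 50 and 0.58 for 1 at 10 RPM. Without the most abundant piRNA, the log2 ratio of the total was -0.97 in the right domain, -0.21 elsewhere on chromosome IV and -0.21 on other chromosomes, where it had been 0.051. The highest minus the lowest abundance class was -1.02 and -0.010 with minimum means of 1 and 50 and -0.64 with 1 RPM. Requiring 10 counts against 0 left 4 piRNAs in the control library alone and 0 in the other.

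Scaled to the listed counts, log2 ratios were 0.077 for let-7, 0.034 for mir-51, -0.11 for mir-58, -0.21 for mir-44, -0.52 for mir-2, 0.23 for the tissue list, 0.065 for microRNA, 1.51 for SL1 RNA, -0.33 for other snRNAs, -0.27 for snoRNA and -0.027 for tRNA, which was -0.082 without its 10 most abundant transcripts. With the median ratio without piRNAs they were 0.23 for let-7, 0.040 for mir-58, 0.38 for the tissue list and 0.21 for microRNA. In first runs alone the values were -0.13 for microRNA, -0.14 for tRNA and 0.56 for other snRNAs, and in second runs alone 0.22 for microRNA and 0.14 for tRNA. Not run were the motif alternatives, the protein-coding lists, single entries per sequence (sequences were not used here) and rescaled known piRNAs, which lie at the floor. Few counts limit what can be said of the mir-35 and lin-4 families and of piRNAs outside the domains; whether depth or the counting keeps them low was not tested.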

Other observations

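The tests on the mir-35 family, on RNA breakdown and on close microRNA gene pairs were chosen only after the results were seen. The scaling to the microRNA total, the total without the 10 most abundant piRNAs and the other snRNA total were fixed before the data were examined, but the limits they were held to were set afterwards. Some microRNAs, picked after their values were seen and with a stricter limit for rises than for falls, stood apart from their class. mir-241 of the let-7 family had 673 and 1745 counts in the control and snpc-4 libraries, a ratio of 2.54 (2.32 to 2.78), while the rest of that family had 1.16 (1.15 to 1.16). mir-355 had 478 and 1012 counts, a ratio of 2.07 (1.86 to 2.31). mir-253 was lower, with 3928 and 2702 counts and a ratio of 0.673 (0.640 to 0.707). Scaled to the listed counts, by the median ratio or to the microRNA total, mir-241 and mir-355 stayed above 1 and mir-253 below 1. Among piRNAs, the 10 most abundant held 35.6% of the class in the control library and 34.0% in the snpc-4 library.

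The left domain had a lower total ratio than the right, 0.374 (0.357 to 0.392) against 0.485 (0.479 to 0.492), and 0.57% of random lists of matched mean had a median at or below its own. From the lowest to the highest abundance class, the left domain had median log2 ratios of -0.94 (-1.70 to -0.71), -1.22 (-2.07 to -0.65), -1.81 (-2.23 to -0.34) and -2.02 (-2.15 to -1.14). The right domain had -0.96 (-1.12 to -0.80), -1.10 (-1.32 to -0.86), -1.12 (-1.27 to -0.99) and -1.25 (-1.34 to -1.09). With 15 to 17 left piRNAs in each class, the intervals overlap in all 4, so where the difference lies is not settled.

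Fewer piRNA reads were counted in the snpc-4 library. Scaling or depth as the whole cause is argued against by the log2 ratio of the piRNA total, which lay -1.25 from that of the microRNA total. A few abundant piRNAs are argued against by the total without the 10 most abundant, at -1.01. Fewer germ cells or oocytes may contribute: the mir-35 family had a ratio of 0.290, on 54 and 16 counts, all in first runs. The piRNAs of other chromosomes had 1.04 (0.944 to 1.14), or 0.866 (0.774 to 0.969) without 21ur-9757. Both ratios for other chromosomes lie above the 0.485 of the right domain. That goes against an even loss of germ cells as the whole cause only if those reads are germline piRNAs, which is not known here. The 11 piRNAs there above the minimum had a median log2 ratio of -0.24 (-1.53 to 0.62). That interval includes the right domain's -1.12, so for other chromosomes it does not settle the point. The 10 piRNAs above the minimum elsewhere on chromosome IV had a median of -0.29 (-0.50 to 0.50). That interval lies above the right domain's, -1.18 to -1.03. Their group's total ratio was 0.735 (0.645 to 0.837), or 0.865 (0.745 to 1.00) without 21ur-14550. These values rest on few piRNAs, and the same condition on germline reads holds for them. An uneven loss, and an effect of snpc-4 on piRNA genes, were not tested and stay open. A difference in size selection between the libraries was not tested either. Reference piRNAs, at 21 nucleotides, lie just under the stated insert range, so the comparison with microRNAs cannot exclude that.

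More SL1 RNA reads were counted in the snpc-4 library. Scaling or depth is argued against by the other snRNAs, whose log2 ratio was -0.20. More RNA breakdown in that library was examined only on tRNA, snoRNA and other snRNA fragments. For these the highest upper bound of a class total was 0.12, against 1.64 for SL1 RNA. It was 0.86 for the few other snRNA reads of first runs. This argues against more breakdown of these classes. Fragments of mRNA and rRNA are not among the listed transcripts, so more breakdown of those was not tested. Breakdown of SL1 RNA alone could still give more short reads, as the inserts are shorter than the whole RNA, and was not tested.

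Transcripts without reads gathered in the first ascending run of each chromosome. The share at 0 was larger in the first run in 22 of 23 pairs of class and chromosome. A candidate explanation is that the runs are the strands and that counting missed most reads of 1 strand. Of 26 microRNA gene pairs starting within 1000 bases of each other, 24 shared a run (92.3%, 74.9% to 99.1%), against 50.3% by chance. Genes made from 1 transcript share a strand. Several pairs can come from 1 gene cluster, so the pairs are not independent and the interval is likely too narrow. The strand is not in the tables used here, neighbours can share other features, and mir-58.1 and mir-229 have many reads in first runs, so this remains a hypothesis; low expression of these genes was not tested.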
